A study of Homo sapiens with 6 samples.

How the data were processed

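Total RNA of SK-N-SH cells was sequenced in 3 untreated and 3 STM2457-treated libraries made with a NEBNext Ultra RNA kit, per the labels' protocols. Groups were taken from the treatment label. The titles of the treated samples give the compound as STM2459 while the treatment label and the series text give STM2457, and the latter was used. The dose is not given in the labels. Per the submitters' processing notes FastQC was run, and the aligner, the counting tool, the genome build and the strand setting are not given in the sources used here. No coordinates are printed for that reason. Genes that share reads with overlapping, antisense or near-identical genes are uncertain.

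Each file gives, per the file headers, a gene symbol, transcript identifiers, a length, an expected count and an FPKM value (fragments scaled by gene length and library depth) for each gene. The expected counts deposited by the authors are estimates, of which 85.9% to 86.6% were whole numbers, and they were rounded to whole numbers here. The FPKM values deposited by the authors were taken as given, and genes below 0.01 FPKM are not listed. A gene missing from one file and listed in another was set to 0. There were 19327 genes in any file and 15655 in all. Biotypes from the RefSeq table of GRCh38.p14, matched by symbol or synonym, were found for 98% of the symbols.

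The comparison of STM2457 with control used edgeR 4.0.16 (R 4.3.3) on the rounded expected counts of all 6 libraries, with TMM factors, filterByExpr (minimum count 10, minimum total 15), default dispersion estimates and the quasi-likelihood test. The design set before the data were examined named limma on log2(FPKM + 1) unless the files held counts, in which case edgeR was the main test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. A robust edgeR fit was looked at before the default fit was settled on, since the design names no robust option, and is given as an alternative. FPKM levels are printed as mean ± SD. The depth of 26605325 to 28917957 counts per library was alike in both groups, and the TMM factors were 0.975 to 1.02. A test on simulated data drew counts for 14379 genes from the real means, library sizes and dispersions, with 200 genes of a mean count of at least 100 changed, in 3 simulations. With 3 against 3 libraries edgeR recovered 16.7% of genes changed 1.25-fold, 78.7% at 1.5-fold, 96.7% at 2-fold and 100% at 3-fold. It made 30 false calls among 468. DESeq2 recovered 31.3% at 1.25-fold, 84% at 1.5-fold and 97.3% at 2-fold, with 77 false calls among 546. The adjusted threshold is easier to reach with 200 genes changed than with few. These shares may therefore be too high for the real data, where fewer genes passed.

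There were 31 gene lists fixed before the data were examined, and 28 had at least 3 tested genes. They were tested with camera of limma 3.58.1 (preset correlation 0.01, all tested genes as background, Benjamini-Hochberg over the lists), again with an estimated correlation, and with fry. The lists cover the m6A writers, the m6A erasers and readers, METTL3-linked genes in leukaemia, interferon-stimulated genes, p53 targets, DNA replication, mitosis, adrenergic, mesenchymal and neuronal identity, ribosome biogenesis, ribosomal proteins, ATF4, ER and heat shock stress, cholesterol synthesis, hypoxia and glycolysis, NRF2 and ferroptosis, AhR targets, NF-kB and cytokines, immediate early genes, extracellular matrix, apoptosis, Wnt, TGF-beta and BMP targets, mitochondrial mRNAs, histones, and leukocyte, epithelial, endothelial and glial markers. Genes were named by a rule set before the data were examined. It took METTL3 and the writers, up to 12 risen and 12 fallen protein-coding genes by fold (adjusted p under 0.05, at least 5 FPKM in the higher group, no overlap of groups), in each list the 3 called genes of smallest adjusted p or else the 2 of highest FPKM, and the 5 most abundant genes. The genes named outside this rule, including members of lists past the list-alone adjustment, were chosen after their values were seen. Some genes of these lists are not reported here by name.

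Alternatives were other size factors, filters, pseudocounts, scalings and weights, DESeq2 1.42.0, limma on FPKM, the replicate number as a block, and each library left out. Those chosen after seeing the data were library totals without TMM, robust estimation, voom with sample weights, and robust estimation without control replicate 1. Exon junctions per kilobase came from GENCODE release 29, matched by symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.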

Results

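RNA sequencing was used to ask which mRNAs change in SK-N-SH cells after exposure to STM2457. SK-N-SH is an established human neuroblastoma cell line known to hold adrenergic cells, which resemble sympathetic neurons, and mesenchymal cells, which grow flat and make matrix. STM2457 is a small-molecule inhibitor of METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. 3 libraries came from untreated cells and 3 from cells exposed for 24 h. Total expected counts per library were 26605325, 28102031 and 27037649 in control replicates 1, 2 and 3, and 28535710, 26965525 and 28917957 in STM2457 replicates 1, 2 and 3. The files list 17109 to 17610 genes per library. The most abundant mRNAs by mean FPKM included RPS27 (a ribosomal protein), TMSB4X (an actin-binding thymosin) and ACTB (actin), at 10953 ± 926, 9310 ± 1214 and 7320 ± 1009 FPKM in the controls and 10254 ± 318, 8916 ± 434 and 8009 ± 348 FPKM after STM2457 (SD, n = 3 each). Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise, and the closest pair, STM2457 replicates 1 and 2, had a chi-square of 2.89 per degree of freedom.

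The untreated libraries were not alike, and control replicate 1 carried a stronger adrenergic programme than the other 5 libraries. CHGA (chromogranin A, a protein of secretory granules) stood at 111 FPKM in that library against 10.04 ± 0.95 FPKM in the others (SD, n = 5). PHOX2A (a transcription factor of sympathetic neurons) stood at 26.8 against 2.79 ± 0.300 FPKM, and DBH (dopamine beta-hydroxylase, which makes noradrenaline) at 26.5 against 4.29 ± 0.566 FPKM. In the same library MFAP5 (a microfibril protein) stood at 2.22 against 22.3 ± 2.33 FPKM and DPT (dermatopontin, a matrix protein) at 14.1 against 103 ± 18.8 FPKM. These 5 genes were chosen after their values were seen. Of 14379 genes, 544 lay at least 2-fold from the mean of the other 5 libraries in control replicate 1, against 111 to 143 in each other library. The first principal component held 47.2% of the variance and set that library apart from the other 5. The second held 18.3% and placed control replicate 3 (24.7) and STM2457 replicate 3 (-18.8) at opposite ends. That pair had a chi-square of 19.7 per degree of freedom, against 2.89 to 11.8 for the other pairs without control replicate 1. The other 5 libraries were thus not alike either. Results that turn on this library are therefore given with it and without it.

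**Figure D1:**
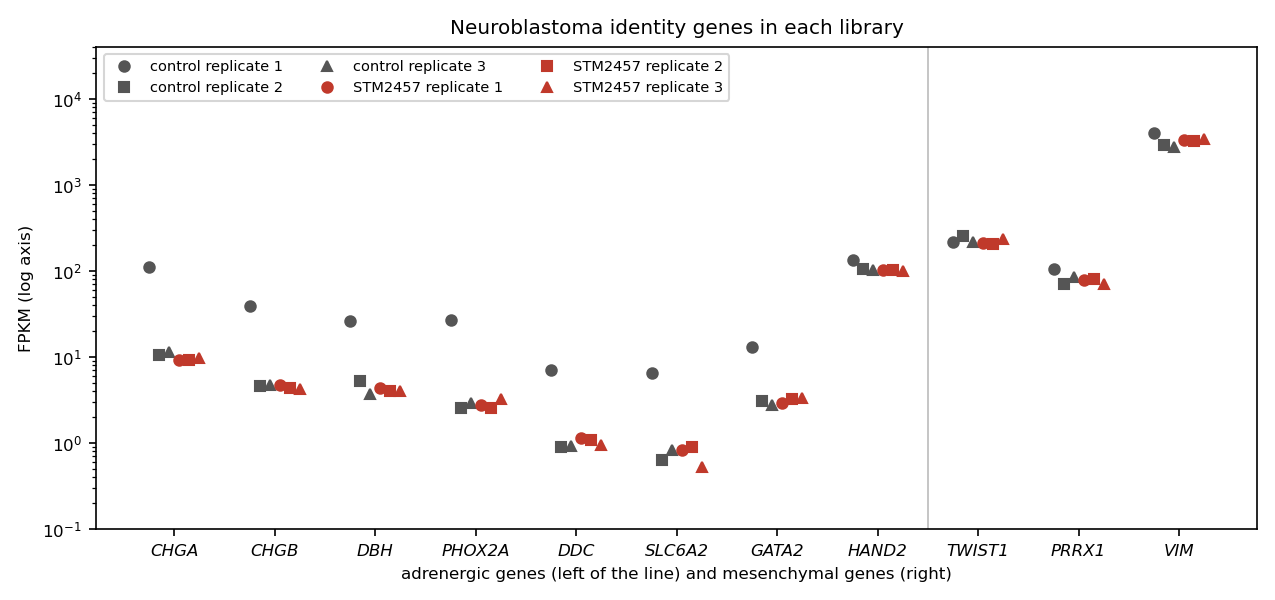
FPKM on a log axis of 8 adrenergic genes and, right of the vertical line, 3 mesenchymal genes, with 1 point per library (grey for control, red for STM2457). Control replicate 1 lies above the other 5 libraries for CHGA, CHGB, DBH, PHOX2A, DDC, SLC6A2, GATA2 and HAND2, with CHGA at 111 FPKM in it. It also lies above them for the mesenchymal genes PRRX1 (104 against 77.3 ± 6.55 FPKM) and VIM (4041 against 3137 ± 274 FPKM). TWIST1 stood at 217 FPKM in it and at 224 ± 19.0 in the others (SD, n = 5).

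With all 6 libraries, 2 genes rose after STM2457 and 0 fell among 14379 tested. IL32, which encodes the pro-inflammatory cytokine interleukin 32, rose from 6.92 ± 1.38 to 23.4 ± 1.43 FPKM (SD, n = 3 each), a log2 fold change of 1.78 ± 0.15 (SE). DOCK2, which encodes an activator of the small GTPase Rac known from leukocytes, rose from 1.71 ± 0.0416 to 3.20 ± 0.278 FPKM (SD, n = 3 each), a log2 fold change of 0.93 ± 0.10 (SE). IL32 was the 1 gene that changed at least 2-fold. The adjusted p in edgeR's quasi-likelihood test (Benjamini-Hochberg) was 0.00604 for IL32 and 0.0312 for DOCK2, which was named after its values were seen because its level falls below the minimum of 5 FPKM set for named genes. At an unadjusted p under 0.05 edgeR gave 440 higher and 427 lower genes, 867 in all. The 6 libraries can be split into 3 and 3 in 9 other ways. Of these splits 3 gave more (1349 to 1523) and the rest gave 200 to 604, so this count is no sign of a treatment effect. The count past the adjusted threshold was 23 higher and 9 lower with DESeq2 and 1 higher and 2 lower with limma on FPKM. On simulated data DESeq2 made 77 false calls among 546 and edgeR 30 among 468. The 3 values of one group lay wholly above or below those of the other for 1649 genes, or 11.5%, where chance gives 10%. IL32 stayed past the threshold without control replicate 1 or 2 and missed it without control replicate 3 or STM2457 replicate 1, 2 or 3, with adjusted p of 0.0782, 0.0754, 0.0574 and 0.0812 in that order, while its log2 fold change stayed between 1.67 and 1.96. DOCK2 stayed past it only without control replicate 1 and had adjusted p of 0.115 to 0.310 without any other library, with log2 fold changes of 0.86 to 0.96.

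**Figure D2:**
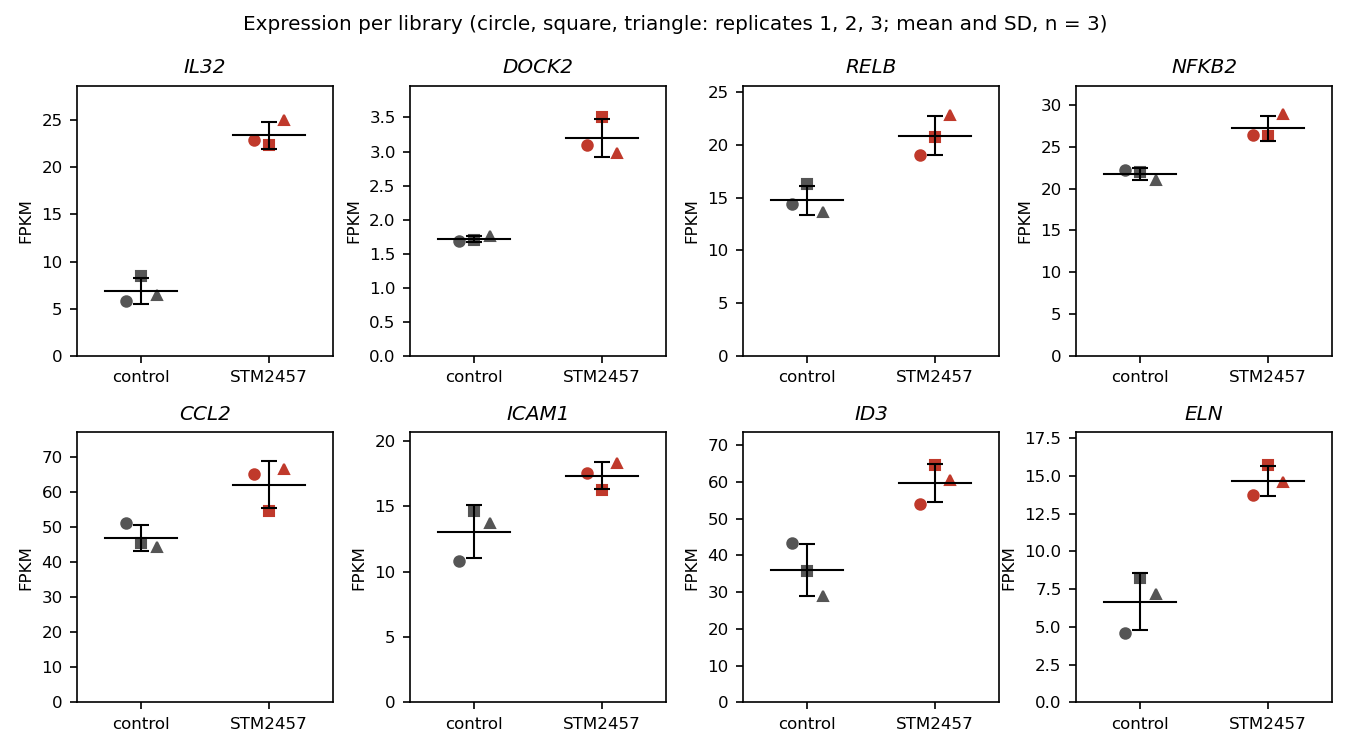
FPKM of 8 genes in each library, with circles, squares and triangles for replicates 1, 2 and 3, and black lines for the mean and SD of each group (n = 3). IL32 stood at 6.92 ± 1.38 FPKM in controls and 23.4 ± 1.43 FPKM after STM2457, and DOCK2, RELB, NFKB2, CCL2, ICAM1, ID3 and ELN are drawn in the same way, each on its own axis from 0.

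METTL3 mRNA, which encodes the enzyme that STM2457 inhibits, did not pass the test. It stood at 44.8 ± 3.67 FPKM in controls and 42.9 ± 1.24 FPKM after STM2457 (SD, n = 3 each), a log2 fold change of -0.04 with a 95% interval of -0.21 to 0.13 and an edgeR adjusted p of 0.940. A compound that blocks the enzyme need not alter its mRNA, so this level checks no label. Of the 8 genes of the writer complex, 0 passed over all genes with edgeR or DESeq2 and 0 with edgeR adjusted over the list alone. METTL14, the partner subunit of METTL3, had a log2 fold change of -0.19 ± 0.10 (SE) and WTAP, the adaptor subunit, 0.01 ± 0.07 (SE). The list had a camera adjusted p of 0.620.

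Genes of NF-kB signalling and inflammatory cytokines were higher together after STM2457. Of 23 listed genes 11 were tested, and all 11 had a positive log2 fold change, with a median of 0.41. RELB and NFKB2, the transcription factor subunits of the non-canonical NF-kB pathway, rose with the test adjusted over the list alone, from 14.8 ± 1.38 to 20.9 ± 1.87 FPKM and from 21.8 ± 0.660 to 27.2 ± 1.501 FPKM (SD, n = 3 each). CCL2 (a chemokine that draws monocytes) rose likewise by 0.41 ± 0.11 on the log2 scale and ICAM1 (a leukocyte adhesion protein) by 0.43 ± 0.12 (SE). In all, 6 of the 11 rose adjusted over the list alone (RELB, NFKB2, CCL2, ICAM1, LIF and IL6) and 0 over all genes with edgeR. IL6 and BIRC3, another tested member, lay under 1 FPKM in both groups. DESeq2 called RELB and NFKB2 over all genes, at adjusted p of 0.0131 and 0.0429. The camera adjusted p was 8.78e-15 with the preset correlation, and the call held at an adjusted p of 0.0445 with an estimated correlation, which was so for no other list. Without control replicate 1 all 11 members stayed above 0 with a median of 0.36, at a camera adjusted p of 6.49e-15 and an adjusted p of 0.125 with an estimated correlation. Fry gave this list an adjusted p of 0.0148 with all 6 libraries and 0.0583 without control replicate 1.

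Small upward shifts covered genes of mitosis, p53 targets and targets of TGF-beta and BMP. Of 38 mitotic genes, 36 had a positive log2 fold change, with a median of 0.15, and 0 passed over all genes with edgeR or DESeq2, or with edgeR adjusted over the list alone. KIF20A, a kinesin of cytokinesis, had a log2 fold change of 0.29 ± 0.07 and PLK1, a mitotic kinase, 0.28 ± 0.07 (SE). Without control replicate 1, 35 of the 38 were positive, and 3 rose adjusted over the list alone. Of 29 p53 targets, 20 were positive with a median of 0.10, and 0 passed either adjustment with edgeR. CDKN1A, the p21 inhibitor of the cell cycle, had a log2 fold change of 0.28 ± 0.07 (SE). Its adjusted p was 0.609 with edgeR and 0.0267 with DESeq2. Without control replicate 1, 26 of the 29 p53 targets were positive and 4 rose adjusted over the list alone. The p53 list then had an adjusted p of 0.0448 in fry and 0.125 in camera with an estimated correlation. Of 14 TGF-beta and BMP targets, 12 were positive with a median of 0.12, and the median was 0.20 without control replicate 1, with 10 of 14 positive. In all, 3 members rose adjusted over the list alone, among them ID3 (an inhibitor of helix-loop-helix factors) and PMEPA1 (a restrainer of TGF-beta signalling), and 0 rose over all genes with edgeR. ID3 went from 36.01 ± 7.08 to 59.7 ± 5.26 FPKM (SD, n = 3 each), and DESeq2 called it over all genes at an adjusted p of 0.000652. The camera adjusted p was 8.78e-15 for mitosis, 2.66e-05 for p53 targets and 1.83e-05 for TGF-beta and BMP targets, and each call was lost, at an adjusted p = 0.199 with an estimated correlation.

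Immediate early genes, extracellular matrix genes, mesenchymal identity genes and both stress lists were also higher by camera. Of 28 immediate early genes, 23 were positive with a median of 0.17 (21 and 0.07 without control replicate 1), and FOSL1, an AP-1 subunit, rose adjusted over the list alone, from 49.0 ± 2.91 to 66.7 ± 5.74 FPKM (SD, n = 3 each). Of 30 matrix genes, 20 were positive with a median of 0.10, and 4 rose adjusted over the list alone, among them COL4A1 and COL4A2 (chains of basement membrane collagen) and FBN1 (fibrillin 1). Of 22 mesenchymal identity genes, 12 were positive with a median of 0.05, and the AP-1 subunits FOSL1 and FOSL2 rose adjusted over the list alone. Of 21 genes of the unfolded protein response of the endoplasmic reticulum (ER) 17 were positive with a median of 0.10 (13 and 0.02 without control replicate 1), and of 25 genes of the ATF4 stress response 19 were positive with a median of 0.06, with 0 past either adjustment with edgeR in both. No member of any of these 5 lists rose or fell over all genes with edgeR. DESeq2 called members of the first 3 over all genes, among them FOSL1, COL4A2 and FBN1 at adjusted p of 0.00622, 0.00447 and 0.0200. The camera adjusted p was 2.95e-05 for immediate early, 2.66e-05 for matrix, 0.0166 for mesenchymal, 0.000653 for ER and 0.0325 for ATF4 genes. With an estimated correlation the adjusted p was 0.199, 0.220, 0.199, 0.514 and 0.468 in that order. Of these 5 lists fry called only the mesenchymal one with all 6 libraries, at an adjusted p of 0.000424. The fry adjusted p of that list was 0.00412 without control replicate 1. Without control replicate 1 the ER and ATF4 calls also ended with the preset correlation, at camera adjusted p of 0.323 and 0.345, and the ATF4 call ended without control replicate 3 (0.0926) or STM2457 replicate 3 (0.0843) and the mesenchymal call without control replicate 2 (0.0803).

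The lists that were lower after STM2457 were adrenergic identity, neuronal differentiation, ribosomal proteins and replication-dependent histones, and each of them was higher in control replicate 1 than in the other 5 libraries. All 20 adrenergic genes had a negative log2 fold change with all 6 libraries, with a median of -0.81, and 0 passed with edgeR over all genes or adjusted over the list alone. DESeq2 gave an adjusted p for 17 of the 20, none past the threshold, and not for CHGA or PHOX2A. The median of the same list lay 1.91 above the other 5 libraries on the log2 scale in control replicate 1. Without that library the adrenergic median was 0.02, with 12 of 20 genes positive, and the camera adjusted p went from 2.66e-05 to 0.598, while with all 6 libraries and an estimated correlation it was 0.514. Neuronal genes had a median of -0.36 with 19 of 22 negative, ribosomal proteins -0.08 with 43 of 44 negative and histones -0.37 with 8 of 10 negative, and without control replicate 1 the medians were -0.03, 0.01 and -0.11. In control replicate 1 these lists had medians 0.70, 0.28 and 0.58 above the other 5 libraries on the log2 scale. Their camera adjusted p was 0.0166, 0.000590 and 0.000259 with all 6 libraries and 0.933, 0.352 and 0.141 without control replicate 1, and with all 6 and an estimated correlation it was 0.499, 0.652 and 0.468. The neuronal call also ended without STM2457 replicate 2 (0.0695) and the ribosomal call without STM2457 replicate 1 (0.237). With all 6 libraries H2AC6, a histone H2A gene of a multigene family whose reads are uncertain, fell adjusted over the list alone. In that fit 0 members of the other 3 lists did.

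**Figure D3:**
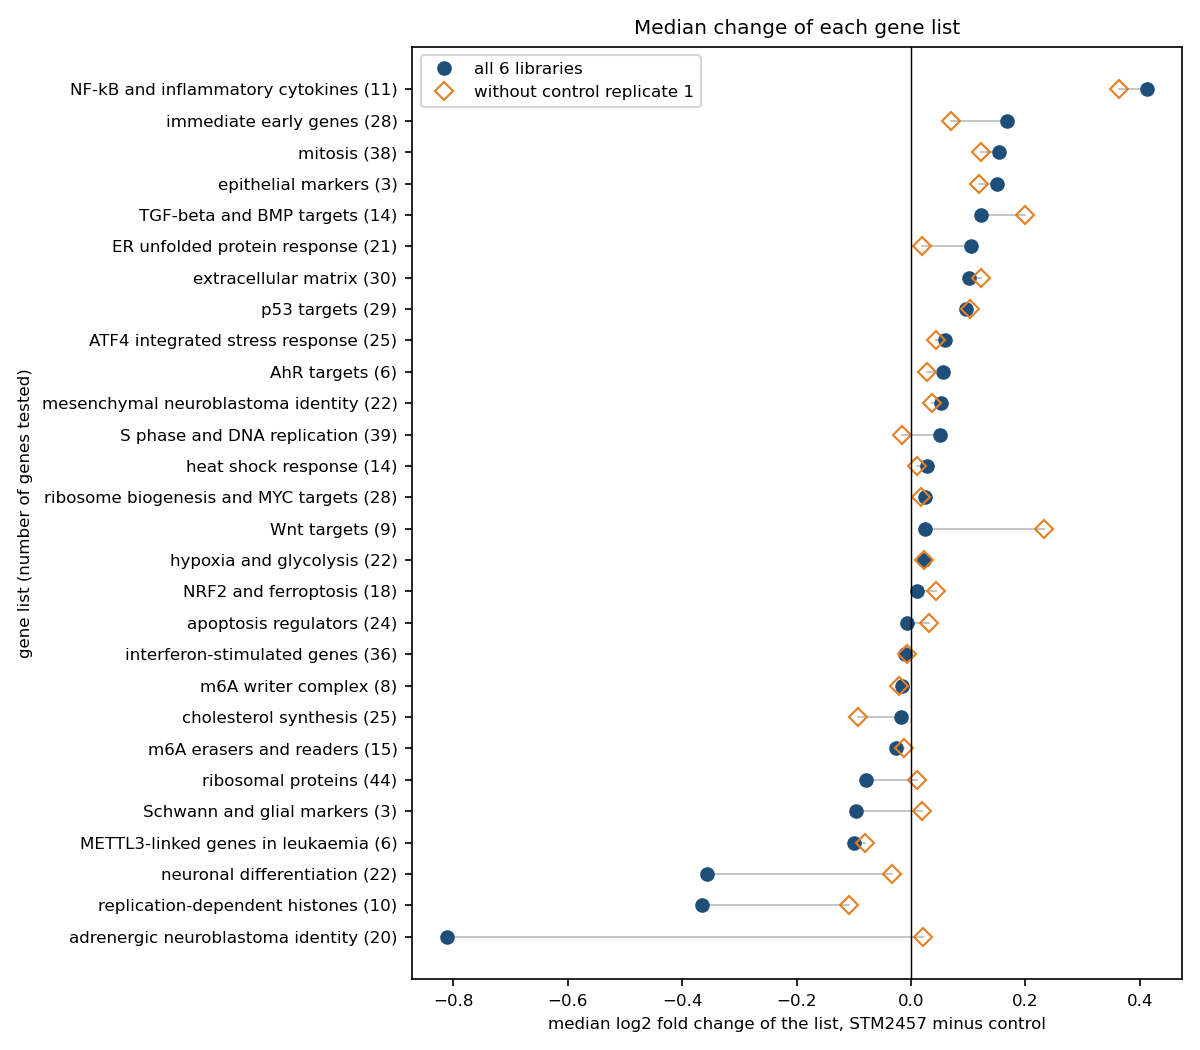
Median log2 fold change (STM2457 minus control) of each gene list with at least 3 tested genes, with all 6 libraries (filled circles) and without control replicate 1 (open diamonds). The adrenergic list moves from -0.81 to 0.02 and the NF-kB list from 0.41 to 0.36.

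Without control replicate 1, and so against 2 controls, genes of the extracellular matrix changed in both directions. Of 14533 genes tested, 26 rose and 10 fell, both IL32 and DOCK2 among those that rose, and 4 rose at least 2-fold. ELN (elastin) rose by 0.94 ± 0.10 on the log2 scale, POSTN (periostin) by 0.79 ± 0.08, ID3 by 0.89 ± 0.12, COL4A1 by 0.43 ± 0.07 and FBN1 by 0.35 ± 0.06 (SE). DCN (decorin) and LUM (lumican), small proteoglycans that bind collagen fibrils, fell with log2 fold changes of -0.72 ± 0.08 and -0.61 ± 0.09, and TNNT2 (cardiac troponin T) with -0.72 ± 0.07 (SE). Of the 30 matrix genes 4 rose and 2 fell over all genes, and 12 rose and 5 fell adjusted over the list alone. The edgeR adjusted p without that library was 0.00115 for ELN and DCN, 0.000735 for POSTN, 0.00646 for ID3, 0.0131 for COL4A1, 0.0174 for FBN1, 0.00737 for LUM and 0.000588 for TNNT2. With all 6 libraries it was 0.157 for ELN, 0.441 for ID3, 0.609 for COL4A1 and FBN1, 0.835 for POSTN and LUM, 0.836 for DCN and 0.914 for TNNT2, and the log2 fold change was 0.44 for POSTN, -0.44 for DCN, -0.39 for LUM and -0.30 for TNNT2. For these 4 genes control replicate 1 lay beyond all 3 STM2457 values on the side away from the other controls, with POSTN at 23.6, DCN at 9.55, LUM at 88.6 and TNNT2 at 72.6 FPKM, against means of 21.4, 11.8, 96.0 and 179 FPKM after STM2457. These genes were named after their values were seen, and the 2 remaining control libraries carry the whole control spread.

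Interferon-stimulated genes did not move as a group. Of 36 tested, 18 were positive and 18 negative, with a median of -0.01 and a camera adjusted p of 0.947. ISG15, a ubiquitin-like interferon product, stood at 46.3 ± 1.90 FPKM in controls and 45.7 ± 4.32 FPKM after STM2457 (SD, n = 3 each). The METTL3-linked genes of leukaemia had a median of -0.10 with 4 of 6 negative and a camera adjusted p of 0.240. With an estimated correlation camera gave 0.473. Fry called this list lower, at an adjusted p of 0.00395 with all 6 libraries and 0.0298 without control replicate 1. Its member MYC (a growth-promoting transcription factor) had a log2 fold change of -0.18 ± 0.10 (SE). The remaining lists did not pass camera either. Medians were 0.05 for DNA replication genes (adjusted p = 0.0730), 0.02 for ribosome biogenesis (0.455), 0.03 for heat shock (0.263), 0.01 for NRF2 and ferroptosis (0.263) and 0.06 for AhR targets (0.499). They were -0.03 for m6A erasers and readers (0.878), -0.02 for cholesterol synthesis (0.794), 0.02 for hypoxia and glycolysis (0.733), -0.01 for apoptosis regulators (0.878) and 0.02 for Wnt targets (0.240), and in these the median differed in sign from the mean or from the test. Without control replicate 1 the Wnt median was 0.23 with 7 of 9 positive (0.155). The DNA replication list passed camera for higher without control replicate 2 (0.0103) or 3 (0.0132), while without control replicate 1 its median was -0.01 with 19 of 39 positive (0.844). The cholesterol list passed for lower without control replicate 1 (0.00789, and 0.297 with an estimated correlation) and for higher without control replicate 3 (0.0495). These left-out calls used the preset correlation, and with all 6 libraries an estimated one gave 0.652 for DNA replication and 0.942 for cholesterol synthesis. Epithelial markers had a median of 0.15 over 3 genes (0.127) and Schwann and glial markers -0.10 over 3 genes (0.947). Several of these medians turned in sign or moved by over 1.5 times with 1 library left out, among them AhR (-0.09 without STM2457 replicate 1 and 0.13 without replicate 2), Schwann and glial (0.06 and 0.05 without the same libraries, 0.02 without control replicate 1) and NRF2 (0.04 without control replicate 1). With all 6 libraries, 0 genes of these lists passed over all genes with edgeR or DESeq2, or with edgeR adjusted over the list alone. CD68 was the 1 leukocyte marker tested, at 10.2 ± 3.06 and 13.2 ± 1.58 FPKM (SD, n = 3 each), with a log2 fold change of 0.40 (edgeR adjusted p = 0.835) and 0.67 without control replicate 1 (0.0595). CD14, of the same list and too low to be tested, stood at 0.403 ± 0.0896 and 0.18 ± 0.128 FPKM (SD, n = 3 each). The 2 endothelial markers tested, ERG and TEK, had means under 1 FPKM in both groups. Mitochondrially encoded mRNAs were not analysed here, as 0 of their 13 genes had values.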

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

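Library totals without TMM, robust estimation, voom with sample weights and robust estimation without control replicate 1 were chosen after the data were seen, and the other settings before. METTL3 stayed short of the threshold in all 26 alternatives (log2 fold change -0.11 to 0.00). The NF-kB list stayed higher and past it in all 27 settings run for it. Without control replicate 1 the NF-kB list missed the threshold in camera with an estimated correlation (adjusted p 0.125) and in fry (0.0583), which are not among them. IL32 passed in 21 of 26, with adjusted p of 1.60e-21 to 0.0812, and DOCK2 in 9 of 24, with 6.16e-08 to 0.310. Against 2 genes higher and 0 lower, edgeR gave 1 and 0 with library totals, with at least 5 FPKM or with adjusted p under 0.01, 5 and 0 with no filter, and 4 and 0 with robust estimation. DESeq2 gave 23 and 9, and voom with sample weights 4 and 2. Limma gave 1 and 2 on log2(FPKM + 1) and with median ratios, 1 and 3 with pseudocounts of 0.1 and 0.5, one total or sample weights, 1 and 1 with quantile scaling, with at least 5 FPKM or without trend and robust, and 0 and 1 with no filter. Its lower calls were H4C8, BMS1P17 and SEMA3B-AS1, a histone, a pseudogene and an antisense gene with uncertain reads. The share of calls that were higher was 100% with edgeR on all libraries, 71.9% with DESeq2 and 25% to 50% with limma where any rose. At 2-fold or more, 1 higher and 0 lower became 5 and 1 with DESeq2, 2 and 1 with voom, 2 and 0 with no filter, 1 and 1 or 1 and 2 with limma (except at 5 FPKM), and 0 and 1 with limma and no filter. Leaving out one library gave 0 to 26 higher and 0 to 10 lower genes, 0 to 4 higher at 2-fold, 7 to 10 lists higher and 1 to 4 lower. The 26, 10, 4, 7 and 1 came without control replicate 1, with or without robust estimation, and that setting kept both calls. Camera with an estimated correlation gave 1 list higher and 0 lower, and fry 2 (mesenchymal, NF-kB) and 1 (METTL3-linked leukaemia genes). Limma at 5 FPKM gave 2 lower. A change of sign was not counted as a turn where a result passed in neither setting. Without control replicate 1 the adrenergic, neuronal and ribosomal lists turned higher by test (the neuronal median stayed at -0.03), short of the threshold, at 0.598, 0.933 and 0.352 (0.597, 0.933 and 0.350 with robust estimation), the cholesterol list turned lower at 0.00789 (0.00760), and DPT and COL10A1 turned to log2 fold changes of -0.45 and -0.37. Without control replicate 2 the matrix median went from 0.10 to 0.20 and the ribosomal one from -0.08 to -0.13, the ribosomal one was -0.05 without STM2457 replicate 1, and the adrenergic one was -1.22 without control replicate 3. Over the libraries left out, DPT ranged from -0.45 to 0.42 and COL10A1 from -0.37 to 0.47, and adjusted p from 1.95e-12 to 0.598 (adrenergic), 8.66e-05 to 0.933 (neuronal), 1.79e-06 to 0.352 (ribosomal) and 0.00789 to 0.901 (cholesterol). The neuronal list also turned, at 0.851 with edgeR and 0.892 with limma, when at least 5 FPKM was asked for and fewer genes were tested. The cause of the other differences was not tested. Replicate numbers did not pair the samples, since same-numbered deviations correlated at -0.00153, -0.0789 and -0.131 across genes and control replicate 2 correlated best with STM2457 replicate 3 (0.171). With the replicate block edgeR gave 4 higher and 0 lower genes, 2 and 0 at 2-fold, and 9 and 4 lists. Of list results 674 kept their side of the threshold without a counted turn, 54 weakened, 4 strengthened and 10 turned. For named genes these counts were 2623, 20, 89 and 4. On simulated data edgeR recovered 16.7% of the smallest simulated changes, 78.7% at 1.5-fold and 96.7% at 2-fold with 3 against 3 libraries, and 38.7%, 88% and 100% with 2 control libraries drawn without control replicate 1. Depth itself was not varied.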

Other observations

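The tests of NF-kB and of the adrenergic list without control replicate 1, of other cell types, of the genes lower in that library, and the split counts for genes were chosen after the result was seen. The tests on other neuronal genes, gene length, exon architecture and the split counts for lists and for the NF-kB median were set before theirs. Control replicate 1 also differed from the other 5 libraries in genes outside the fixed lists, described here as values. VGF, a neuropeptide precursor, stood at 209 FPKM in it and 38.1 ± 7.66 FPKM in the others, and GRP, gastrin-releasing peptide, at 106 and 25.7 ± 1.72 FPKM (SD, n = 5). TNNT2 stood at 72.6 and 226 ± 65.0 FPKM and ANKRD1, a muscle ankyrin repeat protein, at 39.9 and 104 ± 7.15 FPKM (SD, n = 5). These 4 genes were chosen after their values were seen. Among genes of at least 5 FPKM, 52 were at least 2-fold higher and 35 at least 2-fold lower in that library than the mean of the other 5. The other 5 include the 3 treated libraries, so these counts can hold genes that differ by treatment. IL32 is among the lower ones, at 5.81 FPKM in that library against 8.46 and 6.49 FPKM in control replicates 2 and 3.

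IL6R and BDKRB1 did not pass with edgeR and all 6 libraries. IL6R, the receptor of interleukin 6, stood at 1.04 ± 0.116 and 1.77 ± 0.0529 FPKM, and BDKRB1, the inducible bradykinin receptor, at 5.65 ± 0.839 and 11.05 ± 1.75 FPKM (SD, n = 3 each), both with an edgeR adjusted p of 0.157. Without control replicate 1 the edgeR adjusted p was 0.0174 for IL6R and 0.0407 for BDKRB1, and with DESeq2 on all 6 libraries it was 0.00447 and 0.000652, where DESeq2 made 77 false calls among 546 on simulated data. Both were named after their values were seen.

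The adrenergic list was lower after STM2457 with a median of -0.81, and without control replicate 1 the median was 0.0204, so the call rests on that library. In it, 20 of 22 tested neuronal genes from a list of 36 outside the fixed lists were above the other 5 libraries. The median log2 difference of the 22 was 1.46, the direction that a larger share of adrenergic cells in that culture would give. That median rests on genes of low level. Every gene with a difference above 1 had a mean under 1 FPKM in the other 5 libraries. Genes with means of at least 1 FPKM there ranged from -0.36 (CHRNA5) to 0.95 (TAGLN3). Against a gene length bias, removing a trend on gene length left the adrenergic median at 1.88 of 1.91. Other technical causes were not tested. As for other cell types, the summed FPKM of leukocyte, epithelial, endothelial and glial markers was at most 1.05 times the highest other library. In control replicate 1 KRT18 made up 95.4 of the 114 epithelial FPKM and CD68 13.7 of the 14.4 leukocyte FPKM. Such sums cannot exclude a small number of these cells. A larger adrenergic share alone does not account for the genes lower in that library, whose median was -1.36, because mesenchymal identity genes had a median difference of 0.00223 (quartiles -0.16 to 0.10). Whether those cells are a subpopulation of the line or came from another culture, and whether the library is mislabelled, stays open and was not tested.

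The NF-kB list had a median of 0.41 and kept 0.363 without control replicate 1, which argues against that library's composition as the source of its higher level. For this list 1 of 10 splits of the 6 samples into 3 and 3 gave a median as far from 0, the real one, with 0.19 as the highest other. 10 splits are too few for a share under 0.05. A response of this pathway to STM2457 may be proposed as a hypothesis, while solvent or handling differences between the groups and leukocytes in the treated cultures were not tested. Of the leukocyte markers, CD68 had a log2 fold change of 0.40. CD14, too low to be tested, stood at 0.403 FPKM in controls and 0.18 FPKM after STM2457, so these markers do not decide it.

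The count of called genes was 2 for the real split and at most 0 for the others, the count at 2-fold or more 1 and 0, and the count of gene lists past camera 13 and 10. In each case 1 of 10 splits, the real one, reached the real value, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 867 genes. Of the other splits, 3 gave more (1389, 1523 and 1349) and the rest gave 200 to 604. Some groupings other than treatment therefore parted more genes. Other splits gave up to 10 lists, so a list call with the preset correlation was common among groupings that the treatment does not define.

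As a hypothesis, loss of m6A-dependent decay should raise genes with few exon junctions per kilobase, where m6A is known to be denser. Across 12785 genes (88.9% of those tested), which are not independent replicates, Spearman's rho of log2 fold change and junction density was 0.109 with all 6 libraries (bootstrap SD 0.00875) and 0.0995 without control replicate 1. The sign is opposite to the prediction, and another split of the samples reached 0.124, so these data give no sign of that pattern at 24 h.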
